A study of Caenorhabditis elegans with 12 samples.

How the data were processed

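Poly(A) RNA was sequenced from whole Caenorhabditis elegans of the N2 strain at the L4 larval stage, in 12 libraries of about 1000 worms each. The worms had been exposed from the embryo for about 46 h to AO168=O in the agar, at 400, 2000 or 10000 ng/g, or to none, with 0.01% ethanol in all 4 groups and growth at 25 °C. AO168=O is the oxidation product of a phosphite antioxidant used in plastics and belongs to the aryl organophosphate esters. Each group held 3 libraries, which the series describes as independent biological replicates, and the labels put all 12 in the same batch.

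The authors deposited a table of raw read counts per gene and a table of FPKM values for the same libraries. Per the submitters' processing notes, CASAVA, HISAT2 2.2.1, featureCounts 2.0.6 and DESeq2 1.42.0 were used; the notes give no settings. The strand setting, the treatment of reads with several matches and the genome build are not given in the sources used here. Of the 46987 features in the count table, 46926 had the chromosome, start, end and strand of the WBcel235 assembly in Ensembl release 115, and coordinates below refer to that assembly. The other 61 features were predicted loci with no gene name, which held between 0.0167% and 0.0249% of the counts per library. Reads of overlapping genes on opposite strands, and of near-identical gene copies, may have been split in a way that the counts do not show. The deposited FPKM values were used only to check that they came from the same libraries: in each library, the count divided by gene length and FPKM was a single constant to within 4.6e-07 percent over genes with more than 50 counts.

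Total counts ran from 36897811 to 47211800 per library. Two-sided quasi-likelihood tests were run with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors and the low-count filter of that package, which left 16665 genes. A single fit over all 12 libraries with a mean per group gave the 6 comparisons between groups, a test of any difference between the 3 doses and control, and a trend over dose order. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. The common dispersion was 0.0579, a biological coefficient of variation of 24.1%. Expression is given as CPM, the usual unit of counts scaled to the library size, as mean ± SD over 3 libraries. With 3 libraries against 3, an exact test of a single value cannot go below p = 0.1.

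The tests, the alternatives, the rule for named genes and 38 gene lists were fixed before the data were examined. The rule took, per dose, genes past the threshold with a mean of at least 5 CPM and with all 3 exposed libraries beyond all 3 controls, up to the 8 largest rises and the 8 largest falls. It also took up to 2 rising and 2 falling members per list by adjusted p, the 4 acetylcholinesterase genes, and, for a dose with no gene past the threshold, the 5 genes with the smallest unadjusted p. Other genes are said in the text to have been named after their values were seen. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 38 lists and 3 doses. The tests were repeated with a correlation estimated from the libraries and with fry. The list of proteins encoded by the mitochondrial genome matched no gene name, so its 12 genes were taken by chromosome and type, and 11 of them were tested. The pals gene list, a list of other genes of the intracellular pathogen response, the test for an annotated protein signature, the stage covariates and the fit without the libraries at 400 ng/g were chosen after the data were seen.

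The steps were tested on simulated counts drawn from the means and spread of these libraries. In the simulated comparison of 10000 ng/g with control over 16665 genes, edgeR recovered 4.48% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 80.3% of those changed 4-fold, with 2 false calls among 91. DESeq2 recovered 20.9%, 70.1% and 84.8%, with 36 false calls among 153. Alternatives were other scaling factors, no low-count filter, a replicate block, a 2-fold minimum, fits of only the groups compared, dose in ng/g as the trend term, DESeq2 1.42.0, and leaving out each library in turn.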

Results

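The transcriptome of whole L4-stage worms was measured after exposure from the embryo to AO168=O at 400, 2000 or 10000 ng/g of agar, beside a solvent control, with 3 libraries in each of the 4 groups. The series asks which genes respond to this compound at concentrations described as environmentally relevant. Total counts per library ran from 37884563 to 41446642 in the controls, from 40364995 to 47211800 at 400 ng/g, from 37199300 to 38911190 at 2000 ng/g and from 36897811 to 45382586 at 10000 ng/g. Spearman correlations of log2 CPM had a median of 0.988 over the 12 pairs of libraries within a group and of 0.983 over the 54 pairs between groups. All 12 pairs within a group differed by more than counting noise, with a chi-square per degree of freedom of at least 11.98. The first principal component held 31.3% of the variance and the second 24.8%, and replicates 1 and 2 at 400 ng/g lay at opposite ends of the second, at 65.1 and -40.7.

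At 10000 ng/g, genes of the pals family and related genes, a glutathione transferase and enzymes that lengthen branched-chain fatty acids rose. The neighbouring genes ddn-1 (WBGene00015227, chromosome V, 8758820 to 8760516) and B0507.8 (WBGene00015225, chromosome V, 8760622 to 8762961) rose from 5.33 ± 1.48 to 32.2 ± 6.67 CPM and from 4.60 ± 0.398 to 24.5 ± 3.38 CPM (SD, n = 3). These are log2 fold changes of 2.59 ± 0.272 and 2.41 ± 0.252 (SE), each with an edgeR adjusted p of 0.00294. Expression of gst-19, a glutathione S-transferase (WBGene00001767, chromosome II, 13625545 to 13627145), rose from 2.81 ± 0.247 to 10.2 ± 1.34 CPM, a log2 fold change of 1.86 ± 0.19 with an edgeR adjusted p of 0.00294. In all, 35 genes rose and 7 fell among 16665 tested, of which 22 rose and 4 fell at least 2-fold.

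Members of the pals family, genes known from the transcriptional response to intracellular pathogens, made up 7 of the 42 genes past the threshold at 10000 ng/g. The edgeR log2 fold changes were 1.42 ± 0.171 for pals-6 (WBGene00007660, adjusted p = 0.00746), 1.75 ± 0.279 for pals-33 (WBGene00021081, adjusted p = 0.0399) and 1.62 ± 0.29 for pals-14 (WBGene00009061, adjusted p = 0.0476). The deposited gene descriptions give ddn-1, B0507.8 and F42C5.3, the last named after its values were seen, the protein signature of the pals family, ALS2CR12. In total 10 of the 42 genes (23.8%) carried it, against 37 of 16665 tested genes (0.222%), a one-sided Fisher's exact p of 1.08e-18 in a test chosen after these genes were seen. Genes are not independent replicates in that test. The preset list of F-box and pals genes had 7 members that rose among 191, all of them pals genes, and 25 higher and 2 lower when adjusted over the list alone. Its camera adjusted p was 3.39e-06, and the adjusted p was 0.542 with an estimated correlation. Among all 32 tested pals genes, 30 had a positive log2 fold change, with a median of 1.40, and 21 were higher when adjusted over the list alone. Reads of near-identical pals copies cannot be assigned with certainty.

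The elongase genes elo-5 (WBGene00001243) and elo-6 (WBGene00001244), for enzymes that make monomethyl branched-chain fatty acids, rose at 10000 ng/g from 105.7 ± 3.71 to 188.0 ± 18.3 CPM and from 260.9 ± 7.87 to 469.6 ± 39.1 CPM (SD, n = 3). The edgeR adjusted p was 0.0167 for elo-5 and 0.027 for elo-6. In the list of fatty acid synthesis and desaturation genes, 2 of 27 members rose, 5 did so when adjusted over the list alone, and the median log2 fold change was 0.23. The camera adjusted p of that list was 0.000566, and the adjusted p was 0.542 with an estimated correlation. In the list of lipolysis and fatty acid oxidation genes, 0 of 51 passed with edgeR or when adjusted over the list alone, the median was -0.07 with 30 negative, and the camera adjusted p was 0.985. The gene far-3 (WBGene00001387), for a fatty acid and retinol binding protein, rose by a log2 fold change of 1.52 ± 0.253 (edgeR adjusted p = 0.0404), and overlaps far-5. The cuticle collagen gene col-101 rose by 1.25 ± 0.161 on the log2 scale (edgeR adjusted p = 0.0121), and the C-type lectin gene clec-17 by 1.03 ± 0.158 (edgeR adjusted p = 0.0346). The gene col-101 overlaps drl-1, and elo-5 overlaps F41H10.3. The largest rise of a gene named by the preset rule was that of F58E6.4, for a protein with an activin receptor domain, from 2.16 ± 0.569 to 13.5 ± 1.63 CPM (edgeR adjusted p = 0.0139).

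The genes that fell at 10000 ng/g included asb-1, for a mitochondrial ATP synthase subunit of the germ line, from 140.2 ± 4.66 to 93.2 ± 4.22 CPM (SD, n = 3). Its log2 fold change was -0.59 ± 0.0953 with an edgeR adjusted p of 0.0399. The complex I gene nduf-2.2 had a log2 fold change of -0.58 ± 0.0974 (edgeR adjusted p = 0.0404), iff-1, a germ-line translation factor gene that overlaps T05G5.17, of -0.65 ± 0.113 (edgeR adjusted p = 0.0476), and K02E2.8, which overlaps grd-11, of -1.43 ± 0.239 (edgeR adjusted p = 0.0404). In the list of nuclear-encoded respiratory chain genes, asb-1 and nduf-2.2 were the 2 members of 51 that fell, with 4 lower when adjusted over the list alone, a median of -0.04 and a camera adjusted p of 0.137.

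Lists of genes that act on foreign compounds had medians from 0.01 to 0.24 at 10000 ng/g. Among 44 glutathione S-transferase genes gst-19 was the 1 that rose, 2 were higher when adjusted over the list alone, and the median log2 fold change was 0.01 (camera adjusted p = 0.427). Cytochrome P450 genes had a median of 0.11 over 70 genes (camera adjusted p = 0.0357, adjusted p = 0.544 with an estimated correlation) and UDP-glucuronosyltransferase genes of 0.10 over 63 (camera adjusted p = 0.131). The mean log2 CPM of the P450 genes lay from 0.12 to 0.30 above the control mean in the 3 libraries. The control libraries ran from -0.09 to 0.16, so the lowest of the 3 lay inside their range. ABC transporter genes had a median of 0.24 over 49 genes, with 3 higher when adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.544 with an estimated correlation). Leaving out 1 library ended the call of the P450 genes in 3 of 12 fits and of the ABC transporter genes in 7, with a highest camera adjusted p of 0.141 and 0.159. Among 160 cuticle collagen genes, col-101 was the 1 that rose, 4 were higher and 4 lower when adjusted over the list alone, and the median was -0.37 (camera adjusted p = 0.000265, adjusted p = 0.544 with an estimated correlation). Their mean log2 fold change was -0.12. Relative to the control mean, the collagen mean was -0.62, -0.06 and 0.08 in replicates 1, 2 and 3 at 10000 ng/g. The controls ran from -0.29 to 0.50, so only replicate 1 lay below them.

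**Figure D1:**
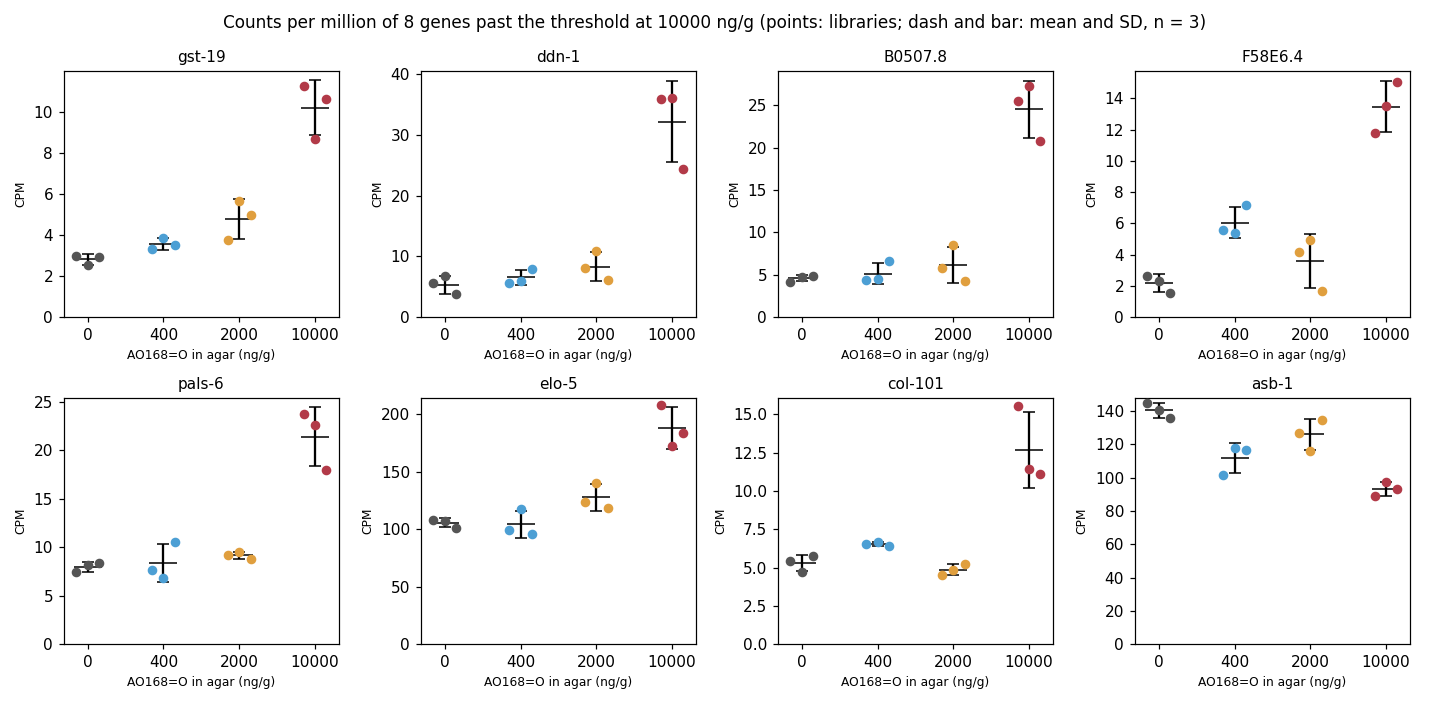
CPM (vertical axes, starting at 0) of 8 genes past the edgeR threshold at 10000 ng/g, by AO168=O concentration in the agar in ng/g (horizontal axes); points are libraries, and the dash and bar are the mean and SD of 3. Mean gst-19 expression was 2.81, 3.55, 4.77 and 10.2 CPM from control to 10000 ng/g, while asb-1 went from 140.2 to 93.2 CPM.

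At 10000 ng/g, 3426 genes had an unadjusted p under 0.05, and 34.3% of genes had all 3 exposed libraries beyond all 3 controls, against 20.4% at 400 ng/g and 11.5% at 2000 ng/g. Chance gives 10% on average over groupings, but genes move together across libraries, so a single grouping can lie far from it. DESeq2 called 478 higher and 495 lower genes, including all 42 edgeR calls. Without 400 ng/g replicate 1, edgeR called 336 higher and 187 lower, and 4 higher and 0 lower without control replicate 1 or without control replicate 3. In 12 fits that each left out 1 library, gst-19, ddn-1 and B0507.8 stayed past the edgeR threshold, with a highest adjusted p of 0.0415. The call of pals-6 was lost in 3, col-101 in 4, elo-5 in 5, F58E6.4 and clec-17 in 6, elo-6 and far-3 in 7, pals-33 in 8, asb-1, nduf-2.2, iff-1 and K02E2.8 in 9, and pals-14 in 10.

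At 400 ng/g, sperm and oocyte genes lay below control, but no gene passed the edgeR threshold. All 39 major sperm protein genes, which encode the cytoskeletal and signalling protein of nematode sperm, had a negative log2 fold change, with a median of -1.83, and 38 were lower when adjusted over the list alone. The list passed the camera test with an adjusted p of 4.09e-24, and had an adjusted p of 0.542 with an estimated correlation. That estimate was 0.84, against the preset 0.01, so these genes moved nearly together across the libraries. Counts of members, here and at the other doses, are therefore not counts of separate observations, and the preset camera p overstates the evidence. Other spermatogenesis genes had a median of -1.47, with 40 of 49 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.08e-18, adjusted p = 0.542 with an estimated correlation). Oogenesis and eggshell genes had a median of -0.86, with 25 of 30 lower when adjusted over the list alone (camera adjusted p = 4.18e-13, adjusted p = 0.544 with an estimated correlation). Adult cuticle genes, which mark the last molt, had a median of -0.96 in the same libraries, with 6 of 9 lower when adjusted over the list alone (camera adjusted p = 0.000371, adjusted p = 0.544 with an estimated correlation). Their mean log2 CPM relative to the control mean was -2.32 in replicate 2 at 400 ng/g, and -0.57 and -0.44 in replicates 1 and 3, inside the control range of -0.71 to 0.89. Without replicate 2 the camera adjusted p was 0.0126. Germ-line genes had a median of -0.33, with 29 of 30 negative and 10 lower when adjusted over the list alone (camera adjusted p = 5.82e-07, adjusted p = 0.544 with an estimated correlation). The 5 genes with the smallest p, none of which passed, all had negative log2 fold changes: ZK84.2 at -1.65 ± 0.248, C09B9.85 at -1.42 ± 0.216, F10D11.3 at -2.47 ± 0.39, the pseudogene WBGene00009411 at -1.62 ± 0.257 and C07E3.4 at -1.31 ± 0.21, each with an edgeR adjusted p of 0.0523.

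Genes of the nervous system had positive medians at 400 ng/g. The median log2 fold change was 0.38 for FMRFamide-like neuropeptide genes, with 28 of 30 positive (camera adjusted p = 5.82e-08, adjusted p = 0.544 with an estimated correlation), and 0.28 for pan-neuronal markers (camera adjusted p = 4.61e-05, adjusted p = 0.542 with an estimated correlation). At 2000 ng/g the neuropeptide genes had a median of -0.05 with 22 of 30 negative, and did not pass (camera adjusted p = 0.543). Nuclear hormone receptor genes had a median of 0.23, over 203 genes, with a camera adjusted p of 1.14e-05 and an adjusted p of 0.542 with an estimated correlation. Cytochrome P450 genes had a median of 0.20 (camera adjusted p = 0.0122, adjusted p = 0.544 with an estimated correlation). In replicates 1, 2 and 3 at 400 ng/g the mean log2 CPM relative to the control mean was 0.55, 0.18 and 0.19 for the neuropeptide genes, -0.09, -0.50 and -0.41 for the germ-line genes, 0.36, 0.13 and 0.10 for the receptor genes, and 0.37, 0.05 and 0.16 for the P450 genes, whose control libraries reached 0.16. Without replicate 1 the camera adjusted p was 0.0218 for the receptor genes, and 0.138 for the P450 genes, which no longer passed.

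At 400 ng/g, 0 genes passed with edgeR, 3084 had an unadjusted p under 0.05 (1129 higher and 1955 lower), and DESeq2 called 250 higher and 1333 lower. The DESeq2 calls held 36 major sperm protein, 36 other spermatogenesis and 15 oogenesis genes. Without the low-count filter edgeR called 54 higher and 876 lower, without 400 ng/g replicate 3 it called 47 and 613, and without 2000 ng/g replicate 3 it called 83 and 820.

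At 2000 ng/g, sperm genes were again on the low side and no gene passed the edgeR threshold. All 39 major sperm protein genes had a negative log2 fold change, with a median of -0.93 (camera adjusted p = 1.5e-14, adjusted p = 0.544 with an estimated correlation), and 0 were lower when adjusted over the list alone. Other spermatogenesis, oogenesis and germ-line genes had medians of -0.567, -0.325 and -0.207 (camera adjusted p = 2.46e-07, 4.91e-05 and 0.000225). With an estimated correlation their adjusted p was 0.585, 0.606 and 0.606. In replicate 3 at 2000 ng/g their mean log2 CPM was 0.03, 0.17 and 0.05 above the control mean. The major sperm protein mean there was -0.26, inside the control range of -0.46 to 0.65. UDP-glucuronosyltransferase genes, for enzymes that conjugate foreign compounds, had a median of 0.21 with 51 of 63 positive (camera adjusted p = 5.82e-07, adjusted p = 0.542 with an estimated correlation). At 400 ng/g their median was 0.25 with 55 positive (camera adjusted p = 0.00071, adjusted p = 0.544 with an estimated correlation), and they did not pass without 400 ng/g replicate 2 (camera adjusted p = 0.0799). Relative to the control mean, their mean was -0.02 in 400 ng/g replicate 1 and 0.11 in 2000 ng/g replicate 3. Both lay inside the control range of -0.15 to 0.20. The 6 vitellogenin genes, for yolk proteins, had a median of 0.80 at 2000 ng/g (camera adjusted p = 0.0313, adjusted p = 0.606 with an estimated correlation). Their mean log2 CPM relative to the control mean spread from 0.62 to 2.62 over the libraries at 2000 ng/g and from -1.67 to 1.85 over the controls. Adult cuticle genes had a median of -0.50 and did not pass (camera adjusted p = 0.0668). Genes of proteins encoded by the mitochondrial genome had medians of 0.17, -0.13 and -0.01 at 400, 2000 and 10000 ng/g, with camera adjusted p of 0.00474, 0.0313 and 0.771, and adjusted p of 0.59, 0.606 and 0.926 with an estimated correlation. Relative to the control mean, their library means ran from 0.15 to 0.25 at 400 ng/g and from -0.17 to -0.09 at 2000 ng/g. The controls ran from -0.23 to 0.18, a range that holds all libraries at 2000 ng/g. The smallest p was that of asns-2, an asparagine synthetase gene, with a log2 fold change of 0.65 ± 0.117, and both copies of rrn-1.1, for 18S ribosomal RNA, followed at -0.91 ± 0.173 and -0.96 ± 0.19. The pseudogene WBGene00004677 had -0.80 ± 0.16 and the kinase gene M05D6.1 -2.0 ± 0.404, all 5 with an edgeR adjusted p of 0.855. Ribosomal RNA made up 0.381 ± 0.0214% of counts at 2000 ng/g, against 0.666 ± 0.0649% in the controls, 0.584 ± 0.102% at 400 ng/g and 0.544 ± 0.0838% at 10000 ng/g (SD, n = 3). With edgeR 0 genes passed at 2000 ng/g and 859 had an unadjusted p under 0.05, while DESeq2 called 1 higher and 4 lower.

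At 10000 ng/g the reproductive lists were also low. No member of the sperm, oogenesis or germ-line lists passed over all genes with edgeR, while DESeq2 called 11 major sperm protein, 13 other spermatogenesis and 10 oogenesis genes. Major sperm protein genes had a median of -1.33, with 39 of 39 negative and 34 lower when adjusted over the list alone (camera adjusted p = 5.69e-14, adjusted p = 0.544 with an estimated correlation). Oogenesis and eggshell genes had a median of -0.73, with 23 of 30 lower when adjusted over the list alone (camera adjusted p = 1.57e-11, adjusted p = 0.544 with an estimated correlation). Germ-line genes had a median of -0.35, with 11 of 30 lower when adjusted over the list alone (camera adjusted p = 5.82e-07, adjusted p = 0.544 with an estimated correlation). Adult cuticle genes, measured in the same libraries, had a median of -1.14 (camera adjusted p = 0.00185, adjusted p = 0.592 with an estimated correlation). All 81 cytosolic ribosomal protein genes had a negative log2 fold change, with a median of -0.25 (camera adjusted p = 4.85e-10, adjusted p = 0.606 with an estimated correlation). Vitellogenin genes had a median of -2.08 and did not pass (camera adjusted p = 0.0577), and their mean ranged between the 3 libraries from -2.77 to -0.64 on the log2 scale.

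**Figure D2:**
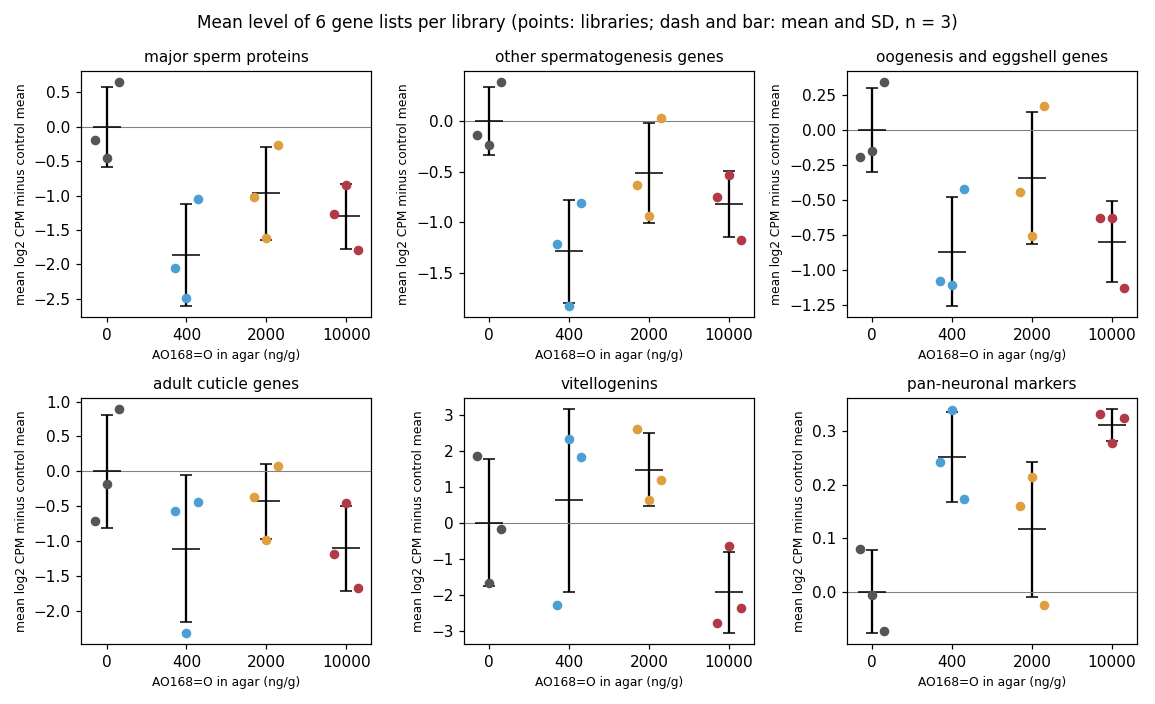
Mean log2 CPM of 6 gene lists per library, minus the control mean (vertical axes), by AO168=O concentration in ng/g (horizontal axes); points are libraries, and the dash and bar are the mean and SD of 3. Among the exposed libraries the major sperm protein mean ran from -2.49 at 400 ng/g replicate 2 to -0.26 at 2000 ng/g replicate 3, and the control libraries ran from -0.46 to 0.65.

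Because organophosphate esters can inhibit acetylcholinesterase, the genes for that enzyme were followed at every dose. At 10000 ng/g the log2 fold changes were 0.59 ± 0.151 for ace-1, 0.15 ± 0.094 for ace-2, 0.27 ± 0.162 for ace-3 and 1.19 ± 0.238 for ace-4, with edgeR adjusted p of 0.103, 0.378, 0.352 and 0.0679. At 400 ng/g they were 0.36, 0.28, 0.09 and 0.80, and at 2000 ng/g 0.19, 0.10, 0.02 and 0.47, and none passed with edgeR over all 12 libraries. DESeq2 called ace-4 at 400 ng/g (adjusted p = 0.0276) and, at 10000 ng/g, ace-1 (adjusted p = 0.0184) and ace-4 (adjusted p = 0.000778). Over all alternatives the adjusted p ran from 0.0276 to 0.777, from 0.0184 to 0.305 and from 0.000778 to 0.294 for these. Without 400 ng/g replicate 1 edgeR also called ace-1 and ace-4 at 10000 ng/g (adjusted p of 0.0275 and 0.0314). Acetylcholine signalling genes had medians of 0.28, 0.18 and 0.28 at 400, 2000 and 10000 ng/g, with camera adjusted p of 0.000355, 0.000178 and 2.02e-05, and an adjusted p of 0.542 with an estimated correlation at each dose. At 10000 ng/g 4 of its 32 members were higher when adjusted over the list alone. The list mean was 0.14 above the control mean in 400 ng/g replicate 1 and 0.05 in 2000 ng/g replicate 3, with controls up to 0.14. Monoamine and GABA signalling genes had medians of 0.23, 0.12 and 0.29 at 400, 2000 and 10000 ng/g (camera adjusted p = 0.000534, 0.0432 and 1e-04). With an estimated correlation their adjusted p was 0.542, 0.544 and 0.542. The positive medians were thus not particular to acetylcholine genes. At 2000 ng/g, pan-neuronal markers had a median of 0.13 (camera adjusted p = 0.00181, adjusted p = 0.544 with an estimated correlation). Body-wall muscle markers had a median of 0.22 at that dose, with 18 of 20 positive (camera adjusted p = 0.000385, adjusted p = 0.606 with an estimated correlation). The muscle call was lost without control replicate 3 (camera adjusted p = 0.0689) and the neuronal call at 2000 ng/g without 2000 ng/g replicate 2 (camera adjusted p = 0.051). At 10000 ng/g, pan-neuronal markers had a median of 0.31 with 8 of 20 higher when adjusted over the list alone (camera adjusted p = 5.21e-06, adjusted p = 0.542 with an estimated correlation).

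Of the 38 lists, 17 passed the camera test at 400 ng/g, 17 at 2000 ng/g and 18 at 10000 ng/g. None held with an estimated correlation, where the smallest adjusted p was 0.542, and none passed with fry, where it was 0.0801. The sign of the median, the mean and the test differed for 5, 9 and 9 lists at the 3 doses, of which only molting cycle genes at 2000 ng/g had passed, with a median of 0.03 and a mean of -0.07.

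In direct comparisons between doses, pals-related genes were higher at 10000 ng/g than at either lower dose in the fit of all 12 libraries. Against 400 ng/g, 16 genes were higher and 0 lower, among them B0507.8 by 2.26, gst-19 by 1.53 and pals-6 by 1.36 on the log2 scale, each with an edgeR adjusted p of 0.0137, and elo-5 by 0.85 (edgeR adjusted p = 0.0198). Against 2000 ng/g, 8 genes were higher and 0 lower, among them B0507.8 by 1.99 and col-101 by 1.38 (edgeR adjusted p = 0.029 each), ddn-1 by 1.96 (edgeR adjusted p = 0.0368) and clec-17 by 1.09 (edgeR adjusted p = 0.0384). At an unadjusted p under 0.05 edgeR gave 830 lower genes against 400 ng/g and 531 against 2000 ng/g, and DESeq2 called 32 and 23 lower. Between 2000 and 400 ng/g edgeR called 0 genes, 1543 having an unadjusted p under 0.05, and DESeq2 called 1 higher. The fit of only the groups compared gave 0 higher genes for 10000 against 400 ng/g, and 519 higher and 382 lower for 10000 against 2000 ng/g. Leaving out 1 library gave 0 higher genes against 400 ng/g without 400 ng/g replicate 2 and without 10000 ng/g replicates 1 or 2. Against 2000 ng/g it gave 0 without control replicate 2, 2000 ng/g replicates 1 or 3, or any replicate at 10000 ng/g.

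Over all doses, 14 genes differed from control in any group, led by B0507.8 and ddn-1 (edgeR adjusted p = 0.00505 each), F42C5.3 (0.00543), gst-19 (0.00553) and T08E11.1 (0.00649), which was named after its values were seen. With dose order as a numeric term, gst-19 alone passed, rising by 0.61 on the log2 scale per step (edgeR adjusted p = 0.013). With dose in ng/g as the term, 46 genes rose and 3 fell, 28 of them among the 42 called at 10000 ng/g. The count for any group fell to 0 without 10000 ng/g replicate 1 and was 184 without 400 ng/g replicate 1. The count for dose order fell to 0 with a replicate block and without 10000 ng/g replicates 1 or 2, and was 12 without 2000 ng/g replicate 3.

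No gene passed the edgeR threshold at more than 1 dose, so the overlap of calls was 0 for each pair of doses. These comparisons share their control libraries. Across genes, which are not independent replicates, the log2 fold changes at 400 and 10000 ng/g correlated at 0.754, against 0.499 in 20 simulations of unchanged groups with shared controls, and their covariance was 0.286 against 0.0776. For 400 and 2000 ng/g the correlation was 0.54 against 0.501 simulated and the covariance 0.149 against 0.0776. For 2000 and 10000 ng/g the correlation was 0.461 against 0.5 and the covariance 0.117 against 0.0782. With 3 controls, which cannot be split into sets of at least 2 libraries each, part of the excess may come from the shared controls. The simulations also drew each gene independently, whereas genes move together across these libraries. They therefore cannot tell a response common to the doses from a structure of the libraries, and no conclusion is drawn from the excess.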

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

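The stage covariates and the fit without the libraries at 400 ng/g were chosen after the data were seen; the other alternatives were planned. For 10000 ng/g against control (35 higher and 7 lower with edgeR), the counts were 12 and 0 with a replicate block, 22 and 4 with a 2-fold minimum, 245 and 186 in a fit of only these groups, 478 and 495 with DESeq2, 18 and 2 with stage covariates and 388 and 221 without the libraries at 400 ng/g; leaving out each library gave 4 to 336 higher and 0 to 187 lower. For 400 ng/g (0 and 0) they were 54 and 876 without the low-count filter, 30 and 549 with a replicate block and 250 and 1333 with DESeq2, and 0 to 83 and 0 to 820 when leaving out each library. For 2000 ng/g only DESeq2 gave calls, 1 and 4, and for 2000 against 400 ng/g it gave 1 higher. For 10000 against 400 ng/g (16 and 0), a replicate block gave 4 higher, a fit of only these groups 0 higher, no filter 2 lower, DESeq2 104 and 32, and leaving out each library 0 to 365 and 0 to 375. For 10000 against 2000 ng/g (8 and 0), a fit of only these groups gave 519 and 382, DESeq2 104 and 23, and leaving out each library 0 to 52 and 0 to 27. The test of any dose (14) gave 49 without the filter, 6 with a replicate block, 1609 with DESeq2, 71 with stage covariates and 0 to 184 when leaving out each library; the trend (1) gave 3, 0, 160, 10 and 0 to 12, and 49 with dose in ng/g. Lists passing (17, 17 and 18) fell to 0 at each dose with an estimated correlation and with fry, and leaving out each library gave 12 to 27, 11 to 20 and 16 to 21. For the ribosomal protein list at 2000 ng/g, the camera adjusted p, given the sign of the direction, ran from -0.748 without 2000 ng/g replicate 3 to 0.213 without control replicate 1, where the direction turned. Median-of-ratios factors kept the side of the threshold of all 38 values of named genes and all 52 lists. The fits on fewer libraries estimate the spread from fewer samples. For 10000 ng/g against control, those with the most calls all left out 400 ng/g replicate 1. Without any other single library the counts were at most 31 higher and 16 lower. The main fit shares a single estimate of the spread over all 4 groups, so the spread at 400 ng/g enters this count. How far it sets the count was not tested, and neither was the cause of the other shifts. Replicate numbers did not pair the libraries: deviations of the 18 same-numbered pairs correlated between -0.471 and 0.339, 5 of them over 0.1, and 3 of 12 libraries correlated best with their own number. All 12 genes called with the block were among the 42. A 1.5-fold change was mostly below what edgeR could call at this depth and spread.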

Other observations

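Of the tests in this part, all but the count of genes near the threshold were chosen after the result was seen, the splits of the libraries included. Genes of the intracellular pathogen response outside the pals family, a list that includes the ubiquitin ligase genes cul-6 and skr-4, had a median log2 fold change of 0.68 at 10000 ng/g, with 18 of 21 positive and 11 higher when adjusted over the list alone. At 400 and 2000 ng/g the medians were 0.14 and 0.10. The camera p at 10000 ng/g was 6.5e-08, and p = 0.000644 with an estimated correlation, for a list written after the pals genes had been seen. No member passed over all genes with edgeR; cul-6 and skr-4, chosen after their values were seen, had log2 fold changes of 0.58 ± 0.187 and 0.56 ± 0.122 (edgeR adjusted p of 0.144 and 0.0832).

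The rise of the pals genes at 10000 ng/g, a mean of 1.38 ± 0.17 (SE) on the log2 scale, was weighed against developmental timing, reads shared between gene copies and infection. With 2 stage components in the model it was 1.47 ± 0.23, which argues against timing, as those components measure it, as its whole cause. The summed CPM of the family also rose, by 1.02 ± 0.167 on the log2 scale, which sharing of reads between copies alone would leave unchanged. The sum cannot tell how many members rose, since reads of a few risen genes may have been counted for their copies. Infection of the cultures remains a candidate explanation: the response genes outside the family rose by 0.833 ± 0.0901, in each of the 3 libraries, and either infection or the exposure could do this, with viral or microsporidian reads not analysed here. A response to the compound remains open beside it.

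The lower sperm genes were weighed against a shift in developmental timing and a smaller germ line. With the adult cuticle score in the model, the difference in the mean of the major sperm proteins at 10000 ng/g went from -1.30 ± 0.512 to -0.55 ± 0.344 (SE), which is consistent with timing at that dose. At 400 ng/g it went from -1.86 ± 0.512 to -1.11 ± 0.344. That argues against timing, as this score measures it, as the whole cause at that dose. The cuticle score averaged -1.11 relative to the control mean at both doses, so the model corrected both alike. Whether what remained differed between the doses was not tested, so no contrast between them is drawn. How fully a score from 9 genes corrects was not tested. Medians of single genes with the 2 stage components went from -1.83 to -0.46 for major sperm proteins. For oogenesis genes the median went from -0.86 to -0.05. As those components are built in part from these genes, that fit tests nothing. Timing as part of the cause stays open at 400 ng/g too. Major sperm proteins fell by 0.978 ± 0.445 more than germ-line genes at 10000 ng/g. An equal loss of germ cells of every kind predicts no such difference. However, the SE is large, and timing, which is open at this dose, could lower sperm genes further than other germ-line genes. The difference therefore cannot decide on a smaller germ line. Whether the compound or the synchronisation of the cultures would shift timing stays open.

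The count at 400 ng/g, 0 genes with edgeR and 1583 with DESeq2, may reflect genes lying just past the threshold. In the edgeR fit 1372 genes had an adjusted p from 0.05 to 0.1. Only a lower bound on that number was predicted, before it was seen but after the smallest adjusted p, 0.0523, was known. Several genes shared that adjusted p, which made a large number likely, so the prediction adds little. Another split of these 6 libraries, with control replicate 1 and 400 ng/g replicates 2 and 3 on one side, gave 2093 genes, which points to a structure of the libraries other than exposure.

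The 3 against 3 comparisons allow 10 splits each, too few for a share under 0.05. For 10000 ng/g against control the real split gave 42 genes and the highest other 0, with 1 of 10 as large; for 10000 against 400 ng/g 16 and 1, with 1 of 10; for 10000 against 2000 ng/g 8 and 0, with 1 of 10. For 400 and 2000 ng/g against control and for 2000 against 400 ng/g the real split gave 0 genes, so that all 10 of 10 splits were as large, and the highest other gave 2093, 0 and 0. Of 100 splits into 4 groups, 3 gave at least the 14 genes of the test of any dose, the highest other giving 19, and 4 gave at least the 1 gene of the trend, the highest other giving 697. Shares this close to 0.05 in 100 draws leave chance open for both, and a split calling 697 genes points to a structure of the libraries.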
